A study of Mus musculus with 36 samples.

How the data were processed

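RNA of whole jejunum was measured on 36 bead arrays, 1 per mouse, in 4 groups set by genotype label (KO or WT) and microbial state (SPF or GF). The tissue was homogenised with a Tissue-Tearor and RNA was extracted with the RNeasy Plus Mini Kit and labelled with biotin, per the labels' protocols. The labels name the MouseRef-8v2 array, whereas the header of the scanner export names M6v2, and both tables hold 45281 probes.

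The values used were those of the deposited value table, linear probe intensities that the authors had background-subtracted and quantile-normalised, as read from the values themselves. Of the intensities 32.0% lay below 0, the range ran from -13.9 to 20319.7, the column medians from 4.4 to 4.5, and the sorted values of the columns differed by at most 0.7. The software behind this table is not given in the sources used here. A scanner export of unnormalised intensities came from GenomeStudio (GSGX Version 1.9.0), per the file headers. Its 144 columns, 4 measures for each of 36 arrays, carry codes that match no sample label, so they were not used. The normexp and quantile processing from detection p-values that had been fixed as the main setting could therefore not be run, and the authors' intensities, first listed as an alternative, became the main values. Alternatives without background correction, with median scaling and with the BeadChip as a block were not run for the same reason.

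Probes were named through a RefSeq gene table (assembly GRCm38.p6, used for names and gene order only). Of the probes, 29370 were named by accession, 863 by gene ID, 3703 by symbol and 3267 by synonym, 18 matched several genes, and 8060 kept the name in the file. Intensities below 0 were set to 0, 16 was added and log2 taken. The background SD, from the values below 0, was 3.98. A probe counted as above background over an intensity of 6.54, which corresponds to a detection p of 0.05, and was kept if it did so on at least 8 arrays. This left 23079 probes. The probe with the highest mean log2 stood for its gene, which gave 15681 genes. For a gene not above background on any array of a group, the fold is a lower bound against the threshold, written "at least". Where only some arrays of a group pass and the group's mean lies under the threshold, the log2 value depends on the offset. This holds for A830030H10Rik, Cyp2b23 and Acot12 in SPF, Rarb and Oas2 in GF and Igkv7-33 in WT. It also holds for Asz1 and 1810065E05Rik in the difference between SPF and GF. No count or depth applies to arrays, and their number limits the precision.

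Differences were tested with limma (version 3.58.1, R 4.3.3) by lmFit and eBayes on all 36 arrays, with a mean per group and a term for sex, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 7 contrasts were KO-labelled against WT in SPF and in GF mice, the difference between those effects, SPF against GF in each genotype, female against male, and the difference of the genotype effect between the sexes. Errors on log2 values are limma's standard errors, and those on intensities are SDs over the arrays of a group. Gata4 was also tested by permutation, two-sided, with 100000 resamples in SPF mice and exactly in GF mice. In all, 32 gene lists written from textbook knowledge were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with an estimated correlation. Over the contrasts of genotype and microbial state, 68 list calls were made with the preset correlation and 15 with the estimated one. A list's score on an array is the mean, over its members, of log2 minus the gene's mean over all arrays.

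The lists, the contrasts, the filter and the rule for naming genes were fixed before the data were examined. The rule names Gata4 and the sex-linked genes, the 8 highest and 8 lowest genes of each contrast of genotype or microbial state (5 and 5 for sex), and up to 3 highest and 3 lowest called members of each list described. Of the genes that this rule named, 3 are not reported here, and no other genes took their place. Which of the lists to describe was decided after their results were seen, and 37 list results are described with their genes. That number was reduced from a larger one after the first count of outlying arrays, so further lists are given as counts, some with their tests, or left out.

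The limma step was tested on simulated data, in which 200 of 15681 genes were changed by log2 values of 0.5, 1 or 2. Noise was drawn as normal and independently for each gene, whereas genes of a real list vary together. Naming, normalisation, floor, offset, filter and choice of probe were not tested, so the simulation speaks for its own setting only. Of the genes called there, the share that had not been changed was 7.5% in SPF, 6.81% in GF, 5% for the difference between them, 3.51% in WT, 5.52% in KO-labelled mice, 7.77% for sex and 3.29% for genotype by sex.

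The alternatives tried were no filter, a filter at 9.25 on 18 arrays, all probes tested separately, no sex term, only the groups compared, array weights, single sexes, GF animals of the same number stem as a block, camera with an estimated correlation, and other probes of named genes. Added after the data were seen were offsets of 1 and 50, no floor, animal 122 entered as female, consecutive animal numbers as pairs, single arrays and the 4 arrays highest in B cell genes left out, and the clock, adipose or interferon score of each array as a covariate. Those scores come from the same arrays' values as the outcome. Permutation tests, scans of neighbouring animals and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The coordinates of the Gata4 probe and of the deleted exons were not available here.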

Results

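Whole-jejunum RNA from 36 mice was measured on Illumina mouse expression bead arrays, 1 array per animal. The mice carried floxed alleles of Gata4, which encodes a zinc-finger transcription factor of the proximal small intestine. KO-labelled animals also carried a Villin-driven Cre recombinase, which acts in the intestinal epithelium, and WT animals were littermates that lacked it. Both genotypes were kept either under specific pathogen-free conditions (SPF, with a microbiota) or germ-free (GF). There were 10 SPF KO-labelled, 10 SPF WT, 8 GF KO-labelled and 8 GF WT mice. Each SPF group held 4 females and 6 males by label, and each GF group held 4 and 4. The design addresses what the jejunal epithelium expresses without GATA4, and whether the answer depends on the microbiota. Values are background-subtracted, normalised probe intensities. Fold changes were computed on the scale log2(intensity + 16), which understates changes of dim genes, and are given with their standard error. Here a gene rose or fell where limma's adjusted p was under 0.05. The number of arrays limits the precision, with a median standard error over 15681 tested genes of 0.107 in the SPF genotype comparison and 0.119 in the GF one.

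Fabp6 and Lct separated every KO-labelled array from every WT array in both microbial states. Across all tested genes, the first principal component held 23.9% of the variance and the second 17.5%. The correlation of log2 values between arrays of the same group had a median of 0.983 over 146 pairs, with a range from 0.969 to 0.993. Between arrays of different groups the median was 0.968 over 484 pairs.

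**Figure D1:**
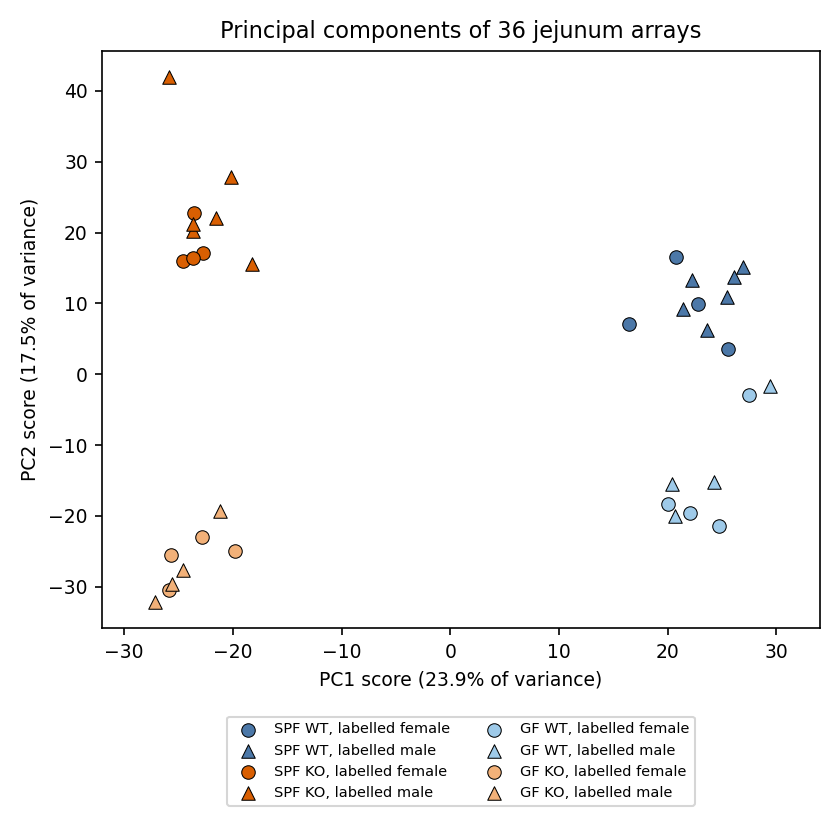
Scores of the 36 arrays on the first and second principal components of all tested genes, in units of log2 intensity, with 1 point per animal coloured by group and shaped by labelled sex. The components hold 23.9% and 17.5% of the variance, and arrays of a group lie near each other apart from single animals.

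Gata4 itself was brighter, not dimmer, in the mice labelled KO. Its probe (ILMN_2817903) had a mean intensity of 47.7 ± 21.3 (SD, n = 10) in SPF KO-labelled and 20.4 ± 9.22 (SD, n = 10) in SPF WT mice, a log2 difference of 0.79 ± 0.17 (limma adjusted p = 0.000723, two-sided permutation p = 0.0003). All 10 of the 10 KO-labelled arrays lay above the WT mean. In GF mice the means were 40.7 ± 13.4 (SD, n = 8) and 25.9 ± 15.5 (SD, n = 8), a log2 difference of 0.48 ± 0.19. That difference did not pass limma's test (adjusted p = 0.0845), while a two-sided exact permutation test of this gene alone gave p = 0.0474, with 7 of 8 KO-labelled arrays above the WT mean. The difference between the GF and SPF effects was 0.31 ± 0.26 (adjusted p = 0.616). Whether the probe lies inside the deleted exons was not known here, and a probe outside them checks nothing about the labels. The groups are therefore called by their labels throughout, and each genotype direction below rests on those labels.

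In SPF jejunum the ileal gene Fabp6 was higher and the jejunal gene Lct lower in KO-labelled mice. Fabp6, the ileal bile acid-binding protein, was 139-fold higher, with a mean intensity of 10949 ± 510 (SD, n = 10) against 73.8 ± 49.6 (SD, n = 10). Lct, the lactase of the jejunal brush border, was 107-fold lower, at 25.6 ± 25.8 (SD, n = 10) against 4029 ± 859.9 (SD, n = 10). Cyp2b10, an inducible cytochrome P450, fell by 6.49 ± 0.20 on the log2 scale and Saa1, an acute-phase serum amyloid A, rose by 5.49 ± 0.47. In all, 3400 of the 15681 genes tested differed, 1874 of them higher and 1526 lower in KO-labelled mice, and 416 differed at least 2-fold (164 higher, 252 lower).

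Among the genes with the highest increases in SPF mice, Suox, the mitochondrial sulfite oxidase, rose by 4.64 ± 0.10, from an intensity of 15.8 ± 6.6 to 764.1 ± 102.9 (SD, n = 10 each). Defcr-rs12, a defensin-related transcript, rose by 2.78 ± 0.60 (adjusted p = 0.000539) and Slc40a1, the iron exporter ferroportin, by 2.77 ± 0.18. Tmigd1, an immunoglobulin-domain adhesion protein of epithelia, rose by 3.40 ± 0.16. The transcripts 1810065E05Rik and A830030H10Rik rose by 4.91 ± 0.22 and 3.0 ± 0.19. In SPF WT mice Saa1, 1810065E05Rik and A830030H10Rik each passed the detection threshold on 5 of 10 arrays, Tmigd1 on 6 and Suox on 9. Among the genes with the largest decreases, Dnase1, a secreted nuclease, changed by -5.37 ± 0.27, the alcohol dehydrogenases Adh1 and Adh4 by -5.01 ± 0.21 and -4.46 ± 0.34, and Cyp2b23 by -4.53 ± 0.21. The nucleoside transporter Slc28a1 changed by -3.83 ± 0.22, and the apolipoprotein Apoa4 by -3.82 ± 0.25, from 15740.4 ± 927.2 to 1306 ± 753.6 (SD, n = 10 each). In SPF KO-labelled mice Cyp2b23 passed detection on 2 of 10 arrays, so its value depends on the offset added, Cyp2b10 on 6, Adh4 on 8 and Slc28a1 on 9. Saa1 was higher in 9 of 10 KO-labelled arrays than in any WT array, and each of the other 15 genes of this group separated the genotypes completely.

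Lipid handling fell as a group in SPF KO-labelled mice. Of 29 measured genes of lipid uptake and chylomicron assembly, 20 fell, 2 rose and 7 did not pass, and adjusted over the list alone 20 fell and 2 rose (median -0.63, camera adjusted p = 9.88e-20, and 5.84e-06 with an estimated correlation). Apoc3, an apolipoprotein that slows triglyceride clearance, changed by -2.63 ± 0.11 and Creb3l3, a transcription factor of apolipoprotein genes, by -2.59 ± 0.13. The desaturases Scd2 and Fads2, which make unsaturated fatty acids rather than absorb lipid, rose by 1.5 ± 0.22 and 1.08 ± 0.11. Of 30 genes of retinoid metabolism, 14 fell and none rose, and adjusted over the list alone 14 fell and 1 rose (median -0.29, adjusted p = 9.6e-10, and 0.000457 with an estimated correlation). They included Rbp2, the cellular retinol-binding protein of enterocytes, at -2.95 ± 0.14. Of 28 genes of xenobiotic metabolism, 19 fell and none rose, and adjusted over the list alone 20 fell and 1 rose (median -1.11, adjusted p = 9.88e-20, and 0.00132 with an estimated correlation). Cyp3a11 changed by -3.54 ± 0.23 and Gstm6, a glutathione transferase, by -2.55 ± 0.13.

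Cholesterol synthesis moved the other way, with 19 of 23 measured genes higher in SPF KO-labelled mice and none lower (median 0.65, adjusted over the list alone 19 higher and 1 lower). Camera gave adjusted p = 4.8e-12, but adjusted p = 0.081 with an estimated correlation. Sqle, squalene epoxidase, rose by 1.83 ± 0.17 and the sterol demethylase Cyp51 by 1.54 ± 0.17. Of 12 genes of ileal bile acid and vitamin B12 uptake, 6 rose and 2 fell, and adjusted over the list alone 6 rose and 3 fell (median 0.15, adjusted p = 0.000231, and adjusted p = 0.0501 with an estimated correlation). Slc51b, a subunit of the basolateral bile acid exporter, rose by 1.96 ± 0.10 and Mep1a, a brush border metalloprotease, by 1.87 ± 0.21. Gucy2c, the guanylin receptor, and Amn, part of the cobalamin receptor, changed by -0.35 ± 0.13 and -0.30 ± 0.07. Of 28 brush border genes 14 fell and 3 rose, and adjusted over the list alone 16 fell and 3 rose (median -0.29, adjusted p = 5.4e-08, and adjusted p = 0.0618 with an estimated correlation). Enpp7, the intestinal alkaline sphingomyelinase, and Slc7a8, an amino acid transporter, changed by -3.66 ± 0.14 and -3.48 ± 0.12. The transporters Slc1a1 and Slc7a9 rose by 1.18 ± 0.08 and 0.60 ± 0.07, and the peptidase Naaladl1 by 1.05 ± 0.14.

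Several immune genes were higher in SPF KO-labelled mice, while other immune lists did not rise: of 20 B and plasma cell genes none passed, of 26 type I interferon genes 1 rose and none fell, and of 21 myeloid and mast cell genes 1 rose and 3 fell, each as adjusted over the list alone (camera adjusted p = 0.427, 0.635 and 0.267). Of 31 genes of MHC class II and the interferon-gamma response, 22 rose and 1 fell, and adjusted over the list alone 26 rose and 1 fell (median 0.86, adjusted p = 2.77e-12, and adjusted p = 0.081 with an estimated correlation). H2-Aa, an MHC class II chain, rose by 2.20 ± 0.32, and the peptide-loading genes H2-DMb1 and H2-DMb2 by 1.98 ± 0.17 and 1.9 ± 0.19. The member that fell, the chemokine Cxcl11, was not above background on any KO-labelled array and was at least 1.07-fold lower. Of 29 epithelial antimicrobial genes, 13 rose and 2 fell, and adjusted over the list alone 16 rose and 2 fell (median 0.34, adjusted p = 0.000231, and adjusted p = 0.27 with an estimated correlation). Ubd, a ubiquitin-like protein induced by cytokines, rose by 2.35 ± 0.53 and Duoxa2, the maturation factor of the dual oxidase, by 2.32 ± 0.32. The cytokine Il18 and the lectin Reg3a changed by -0.93 ± 0.14 and -0.43 ± 0.12. A second probe of Il18 gave 0.027 ± 0.11 (adjusted p = 0.916).

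Of 29 genes of T cells and intraepithelial lymphocytes, 13 rose and 2 fell in SPF KO-labelled mice, and adjusted over the list alone 15 rose and 2 fell (median 0.41, adjusted p = 0.000231, and adjusted p = 0.27 with an estimated correlation). Cd6, a surface receptor of T cells, rose by 1.76 ± 0.25, and the kinase Lck and the granule protein Nkg7 by 0.76 ± 0.20 and 0.76 ± 0.14. Klrd1, a natural killer receptor, changed by -0.41 ± 0.13. KO-labelled animal 114 had the highest T cell score of its group and a B cell score of 2.52, against a group median of 0.0635. Of 25 enteroendocrine genes, 4 rose and 5 fell, and adjusted over the list alone 5 rose and 8 fell (median 0.01, camera adjusted p = 0.598). The list's mean and camera's direction were downward, unlike its median. Pyy, a hormone of the distal gut, rose by 1.30 ± 0.13, the fatty acid receptor Ffar4 by 1.06 ± 0.14 and secretin, Sct, by 0.46 ± 0.07. The upper-gut hormones Gip and Cck changed by -1.64 ± 0.11 and -0.92 ± 0.17, and Sst, somatostatin, by -0.83 ± 0.11. All limma and camera tests used all 36 arrays with sex as a covariate. The simulation of this comparison recovered 80.6% of genes changed by 0.5 on the log2 scale, 97.0% of those changed by 1 and 100% of those changed by 2.

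In GF jejunum, without a microbiota, Fabp6 and Lct again separated the genotypes. Fabp6 was 97.1-fold higher in KO-labelled mice, at 10078 ± 622 against 100.3 ± 63.3 (SD, n = 8 each), and Lct was 91.2-fold lower, at 27.8 ± 24.8 against 3442 ± 587.4 (SD, n = 8 each). Dnase1 changed by -6.18 ± 0.30 and Asah2, the brush border neutral ceramidase, by -5.06 ± 0.16, from 5174 ± 481.7 to 144.6 ± 46.3 (SD, n = 8 each). Type I interferon genes were lower in GF KO-labelled than in GF WT mice, but only 5 of 8 GF WT arrays had a raised score and the list did not pass camera with an estimated correlation (adjusted p = 0.307). Of the 15681 genes, 3091 differed (1824 higher, 1267 lower), 476 of them at least 2-fold (172 higher, 304 lower).

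Of the other GF genes with the highest increases, Suox rose by 4.38 ± 0.12, Defcr-rs12 by 4.16 ± 0.67 (adjusted p = 9.75e-06), Tmigd1 by 3.57 ± 0.18, and Cutal, a protein related to bacterial copper tolerance factors, by 3.12 ± 0.17. The beta-defensin Defb37 rose by 3.06 ± 0.18 and the copine Cpne8 by 3.05 ± 0.11. Slc25a48, a mitochondrial carrier, passed detection on 0 of 8 GF WT arrays and was at least 7.44-fold higher in KO-labelled mice. Saa1 was likewise not above background on any GF WT array and was at least 2.31-fold higher. Cyp2b10, Adh1, Cyp2b23 and Adh4 changed by -6.38 ± 0.22, -4.78 ± 0.24, -4.75 ± 0.24 and -4.15 ± 0.38, and Enpp3, an ectonucleotidase, by -4.62 ± 0.20. Cyp2b23 passed detection on 2 of 8 KO-labelled arrays, Adh4 on 4, and Cyp2b10 and Lct on 6, and in GF WT mice Tmigd1 passed on 6 of 8 and Defb37 and Cpne8 on 7. Each of these genes separated all 8 KO-labelled from all 8 WT arrays.

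Of the 29 lipid genes, 21 fell and 2 rose in GF KO-labelled mice, and adjusted over the list alone 21 fell and 4 rose (median -0.61, adjusted p = 7.66e-18, and 1.39e-05 with an estimated correlation). Apoa4 changed by -3.49 ± 0.28, Apoc2, the activator of lipoprotein lipase, by -2.57 ± 0.31 and Apoc3 by -2.19 ± 0.12, while Fads2 and Scd2 rose by 1.74 ± 0.13 and 0.75 ± 0.25. Of the 12 ileal genes, 6 rose and none fell, as adjusted over the list alone (median 0.45, adjusted p = 5.44e-07, and 0.00675 with an estimated correlation). They included Nr1h4, the bile acid receptor FXR, at 2.09 ± 0.09, and Slc51b at 1.70 ± 0.11. Of the 30 retinoid genes, 9 fell and 2 rose, as adjusted over the list alone (median -0.09, adjusted p = 0.000266, and 0.0372 with an estimated correlation). Rbp2 changed by -2.25 ± 0.15, and the nuclear receptors Rxra and Rarb rose by 0.58 ± 0.10 and 0.45 ± 0.12, with Rarb detected on 2 of 8 GF WT arrays. Of the 28 xenobiotic genes, 18 fell and 1 rose, and adjusted over the list alone 19 fell and 2 rose (median -0.88, adjusted p = 4.17e-14, and 0.00908 with an estimated correlation). Cyp3a11 and Gstm6 changed by -3.45 ± 0.25 and -2.24 ± 0.14, and the quinone reductase Nqo1 rose by 0.39 ± 0.14.

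Cholesterol genes rose in GF KO-labelled mice too, 17 of 23 with none lower, and adjusted over the list alone 18 (median 0.72, adjusted p = 5.85e-11, and adjusted p = 0.134 with an estimated correlation). Sqle rose by 1.49 ± 0.19 and Cyp51 by 1.36 ± 0.19. Of the 28 brush border genes, 14 fell and 5 rose, and adjusted over the list alone 15 fell and 5 rose (median -0.34, adjusted p = 4.73e-06, and adjusted p = 0.134 with an estimated correlation). Some markers of other tissue layers rose: of 19 smooth muscle genes 9 rose and 1 fell, and adjusted over the list alone 12 and 1 (median 0.28, adjusted p = 0.00367, and adjusted p = 0.402 with an estimated correlation), and of 13 enteric neuron and glia genes 4 rose and 1 fell, as adjusted over the list alone (adjusted p = 0.118). Slc2a2, the basolateral glucose transporter, changed by -4.04 ± 0.28 and Enpp7 by -2.60 ± 0.16. Naaladl1, Slc1a1 and the anion exchanger Slc26a6 rose by 1.80 ± 0.15, 1.49 ± 0.09 and 0.58 ± 0.10. Of the 25 enteroendocrine genes, 5 rose and 3 fell, and adjusted over the list alone 6 rose and 3 fell (median 0.07, adjusted p = 0.77). Pyy and Ffar4 rose by 1.45 ± 0.15 and 1.13 ± 0.15, and Gip, Cck and Sst changed by -1.68 ± 0.12, -1.20 ± 0.19 and -1.20 ± 0.12. Nts, neurotensin, rose by 0.78 ± 0.20, but another probe of it gave -0.015 ± 0.13 (adjusted p = 0.963).

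Of 26 type I interferon genes, 21 were lower in GF KO-labelled than in GF WT mice and none higher, and adjusted over the list alone 24 were lower (median -1.23, adjusted p = 1.9e-11, and adjusted p = 0.307 with an estimated correlation). The antiviral genes Oas2, Isg15 and Usp18 changed by -2.74 ± 0.68, -2.61 ± 0.48 and -2.44 ± 0.53, and Oas2 passed detection on 3 of 8 GF KO-labelled arrays. The levels in GF WT mice were uneven: 5 of 8 GF WT arrays and 0 of 8 GF KO-labelled arrays had an interferon score above 0, as did 2 of 10 arrays in each SPF group. Of the 31 genes of MHC class II and the interferon-gamma response, 11 fell and none rose in GF KO-labelled mice, and adjusted over the list alone 12 fell (median -0.43, adjusted p = 5.44e-07, and adjusted p = 0.285 with an estimated correlation). The GF WT arrays were uneven in this list too: 17.1 and 11.1, the 2 with the highest B cell scores, stood at 0.495 and 0.173. Arrays 15.1, 14.1 and 10.1, with low B cell scores of -0.460, -0.626 and -0.442, stood at -0.0109, -0.187 and -0.366. These 5 were the GF WT arrays with an interferon score above 0. The other GF WT arrays, 12.1, 13.1 and 16.1, stood at -0.559, -0.564 and -0.596, next to or inside the GF KO-labelled range of -0.819 to -0.586. The interferon-inducible GTPases Igtp and Irgm2 changed by -2.0 ± 0.41 and -1.45 ± 0.32, and the immunoproteasome subunit Psmb8 by -1.25 ± 0.14. The simulation of the GF comparison recovered 67.2% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1 or 2.

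**Figure D2:**
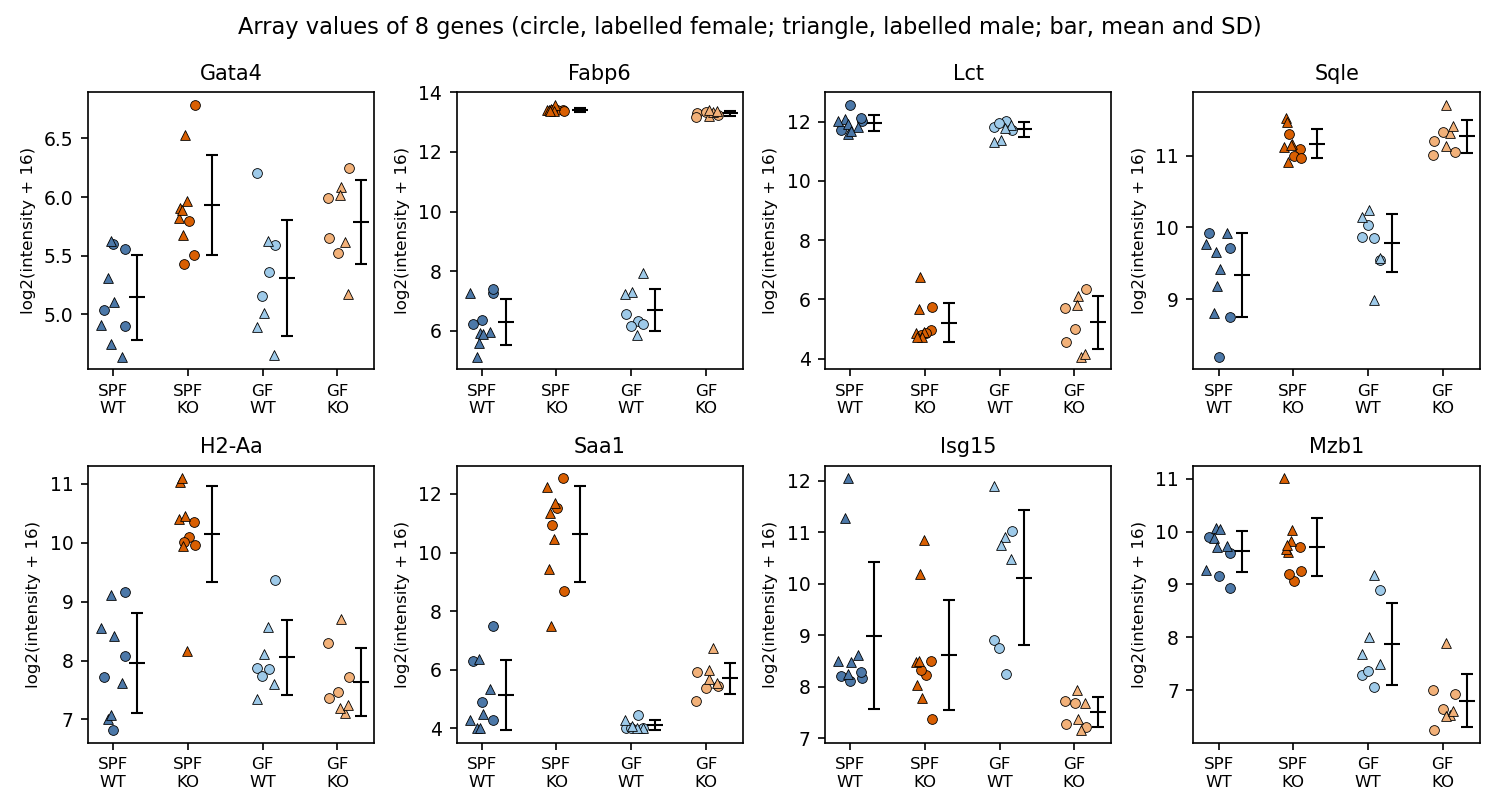
Values of Gata4, Fabp6, Lct, Sqle, H2-Aa, Saa1, Isg15 and Mzb1 on the log2(intensity + 16) scale, 1 point per array by group, with group means and SD as bars. Fabp6 and Lct separate KO-labelled from WT arrays in both microbial states, whereas Saa1 reaches a mean intensity of 2418 in SPF KO-labelled mice and of 39.6 in GF KO-labelled mice.

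The next comparison asked whether the genotype effect depended on the microbial state. Several inflammatory genes had a genotype effect that was higher in SPF than in GF mice, whereas for Fabp6, Lct and Cyp2b10, which changed in the same direction in both states, the difference did not pass. Saa1 differed by 3.89 ± 0.71 on the log2 scale (adjusted p = 0.000807). Its mean intensity was 34.3 ± 51.5 in SPF WT, 2418 ± 1916 in SPF KO-labelled (SD, n = 10 each), 1.2 ± 2.2 in GF WT and 39.6 ± 23.1 in GF KO-labelled mice (SD, n = 8 each). Since no GF WT array was above background, its fitted GF effect depends on the offset added, and so does this difference. Ubd differed by 3.70 ± 0.80, Igtp by 3.33 ± 0.55, Irgm2 by 2.74 ± 0.43, H2-Aa by 2.62 ± 0.48 and the interferon-induced Ifit2 by 2.45 ± 0.61. Of 26 type I interferon genes, 6 had a higher effect in SPF and none a lower one, and adjusted over the list alone 17 (median 1.10, adjusted p = 1.66e-14, and adjusted p = 0.256 with an estimated correlation), and 5 of 8 GF WT arrays had a raised interferon score. The transcripts OTTMUSG00000016644 and Gm12250 differed by 2.64 ± 0.47 and 2.38 ± 0.48.

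Genotype effects were compared over all genes first. The SPF and GF effects, which share no arrays, correlated across genes with Pearson's r = 0.697 (SD over resampled animals 0.0382) and Spearman's rho = 0.427, although genes are not independent replicates. Of the genes tested, 1773 differed in both states, and 1729 of these in the same direction, 919 higher and 810 lower, where independent lists would share 218.0 and 123.3. The test of the difference itself called 581 genes, 284 with a higher and 297 with a lower effect in SPF, and 153 differed at least 2-fold (110 higher, 43 lower). Of the 284, 134 were called higher in SPF mice and not called in GF mice, 85 lower in GF mice and not called in SPF mice, and 26 higher in SPF and lower in GF mice. Of the 297, 111 were called higher in GF mice and not called in SPF mice, 84 lower in SPF mice and not called in GF mice, and 45 higher in both.

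Of the genes whose effect was lowest in SPF relative to GF mice, Slc28a1 differed by -1.95 ± 0.32 and Defb37 by -1.84 ± 0.24. The cytochromes P450 Cyp4f16 and Cyp2d40 differed by -1.82 ± 0.24 and -1.74 ± 0.18. Cyp4f16 had an intensity of 1772 ± 829.2 in SPF WT and 864.7 ± 170.1 in SPF KO-labelled mice, against 920.8 ± 207.5 and 1706 ± 359.2 in the corresponding GF groups (SD). Ifi202b, an interferon-inducible DNA sensor, differed by -1.69 ± 0.36, the SOCS-box protein Spsb4 by -1.60 ± 0.35, the scramblase Plscr4 by -1.60 ± 0.22 and the germ-cell protein Asz1 by -1.56 ± 0.26. Asz1 passed detection on 3 of 10 SPF WT and 2 of 8 GF WT arrays, and Defb37 on 4 of 10 SPF WT arrays.

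The MHC class II and interferon-gamma genes differed most as a list, with a higher genotype effect in SPF for 24 of 31 and a lower one for none, and adjusted over the list alone for 26 (median 1.44, adjusted p = 4.87e-44, and 0.000766 with an estimated correlation). In GF WT mice the arrays with an interferon score above 0 were also the highest in this list. For T cells it was 13 of 29 genes, and adjusted over the list alone 18 (median 0.78, adjusted p = 1.09e-14, and 0.0193 with an estimated correlation), with Cd6 at 2.24 ± 0.38, the chemokine Ccl5 at 1.53 ± 0.26 and Nkg7 at 1.38 ± 0.21. GF WT arrays 17.1 and 11.1 stood apart in this list as well, with scores of 0.189 and 0.143 against -0.605 to -0.365 in the other 6 GF WT arrays. For the cell cycle it was 12 of 29 genes, and adjusted over the list alone 24 (median 0.44, adjusted p = 1.79e-19, and 0.0413 with an estimated correlation). The mitotic kinase Plk1 differed by 0.68 ± 0.18, the replication helicase subunit Mcm5 by 0.66 ± 0.14 and Birc5, survivin, by 0.65 ± 0.14. Of 29 antimicrobial genes, 9 had a higher and 2 a lower effect in SPF, and adjusted over the list alone 13 and 3 (median 0.55, adjusted p = 5.69e-06, and adjusted p = 0.256 with an estimated correlation). Duoxa2 differed by 1.91 ± 0.48, and the lectins Reg3b and Reg3a by -1.25 ± 0.28 and -0.83 ± 0.17.

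Of 28 brush border genes, 2 had a higher and 4 a lower effect in SPF, and adjusted over the list alone 2 and 5 (median -0.13, adjusted p = 0.107). Slc2a2 differed by 2.10 ± 0.38 and the protease Mep1b by 0.29 ± 0.08, and Slc7a8, Enpp7 and Slc26a6 by -1.16 ± 0.18, -1.05 ± 0.22 and -0.78 ± 0.13. The count of 581 fell to 341 without the 4 arrays highest in B cell genes and to 296 with the interferon score of each array as a covariate. The simulation recovered 37.3% of genes whose effects differed by 0.5, 91.0% of those differing by 1 and 100% of those differing by 2.

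**Figure D3:**
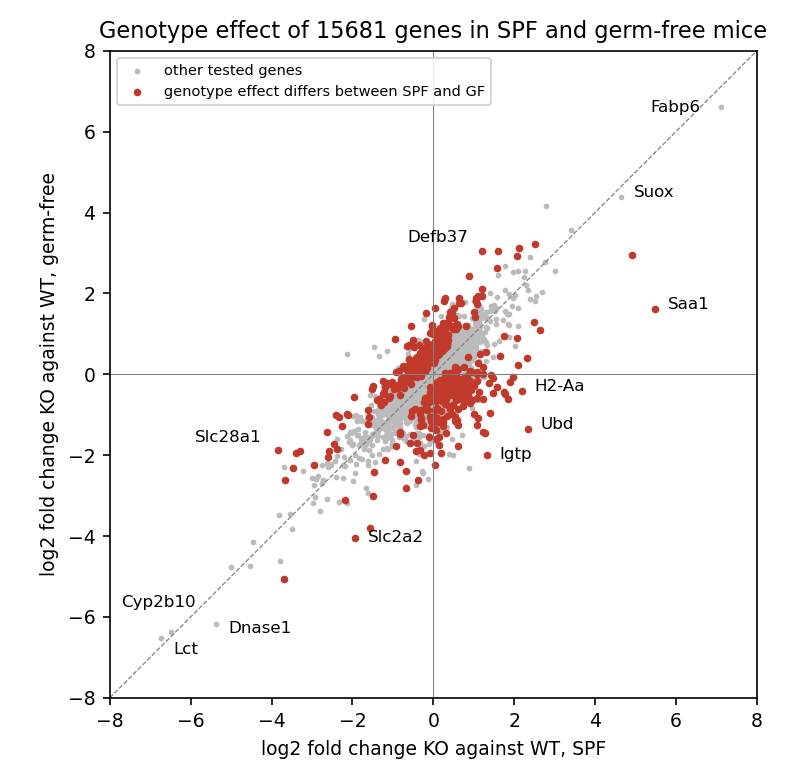
Log2 fold change of KO-labelled against WT mice for 15681 genes, in SPF mice on the horizontal and GF mice on the vertical axis, with the line of equal effects dashed and the 581 genes whose effects differ in red. Fabp6, Suox, Lct and Cyp2b10 lie near the line, and Saa1, Ubd, Igtp and H2-Aa lie to the right of it.

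**Figure D4:**
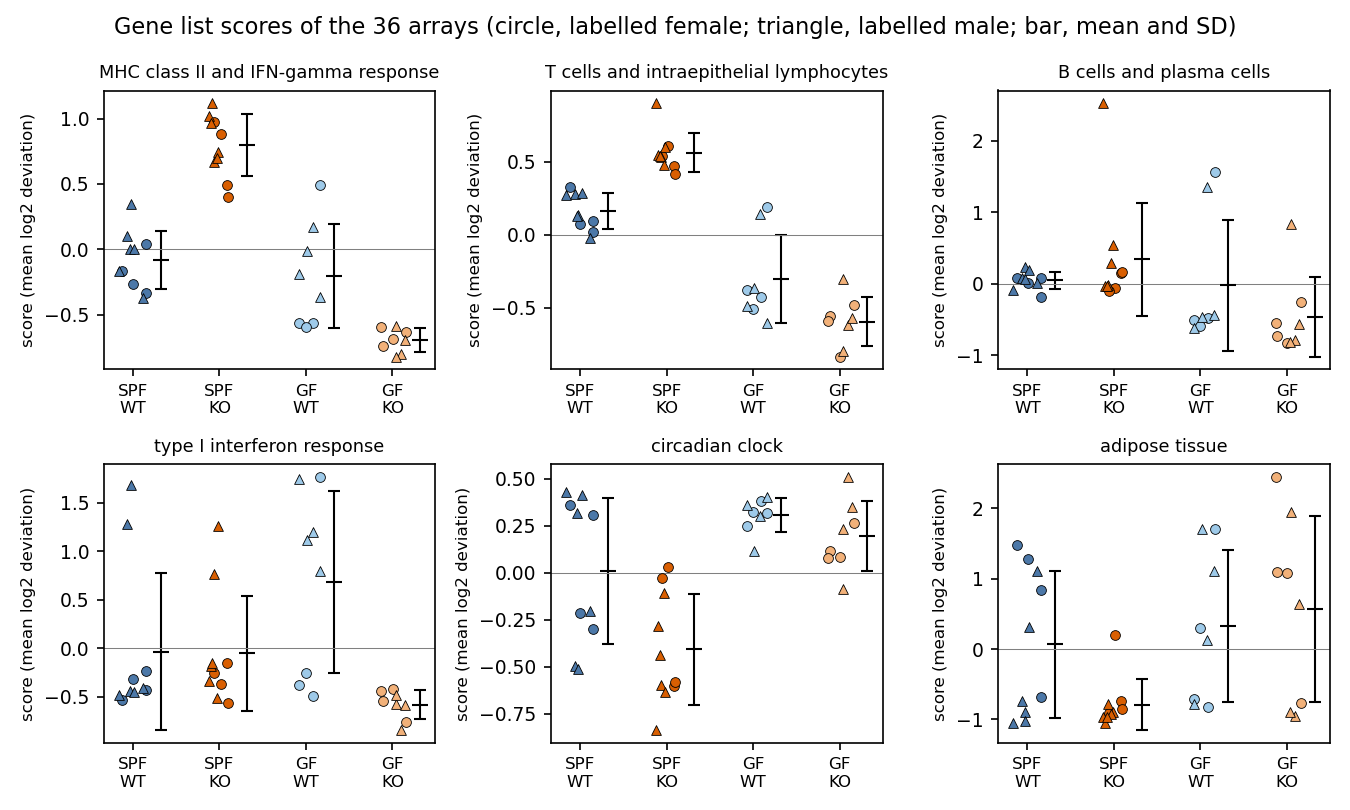
Scores of 6 gene lists on the 36 arrays, each the mean log2 deviation of the list's members from their means over all arrays, with 1 point per array and bars for group means and SD. The MHC class II score runs from 0.399 to 1.12 in SPF KO-labelled mice and from -0.819 to -0.586 in GF KO-labelled mice.

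SPF and GF mice were then compared within each genotype. They are separate sets of animals. The microbiota therefore cannot be told apart from colony, time of collection or other conditions that differ between the sets. In WT mice, several antibody variable-region transcripts, 14 of 29 T cell genes and the lectins Reg3g and Reg3b were higher in SPF than in GF animals, and the glutathione transferases Gsta1, Gsta2 and Gsta3 were lower. The T cell list did not pass camera with an estimated correlation (adjusted p = 0.0599). The immunoglobulin kappa segment IGKV11-125 was 14.9-fold higher, at 1091 ± 1140 (SD, n = 10) against 49.2 ± 43.7 (SD, n = 8), and was higher in all 10 SPF arrays than in any GF array. Reg3g, a lectin that kills Gram-positive bacteria, rose by 1.68 ± 0.20 and its relative Reg3b by 1.26 ± 0.20. In WT mice 1185 genes differed, 615 higher and 570 lower in SPF, 128 of them at least 2-fold (91 higher, 37 lower).

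The 8 highest differences in WT mice were immunoglobulin segments or unnamed loci. LOC384415, LOC100046552 and LOC636875 rose by 3.58 ± 0.53, 3.30 ± 0.49 and 3.14 ± 0.84. IGKV12-98, IGHV2S1, Ighv1-84 and IGKV8-31 rose by 3.12 ± 0.89, 2.99 ± 0.39, 2.83 ± 0.39 and 2.76 ± 0.38. The segment Igkv7-33 went the other way, by -3.42 ± 0.34, a value that depends on the offset, since it passed detection on 2 of 10 SPF WT arrays. In GF WT mice IGHV2S1 passed detection on 5 of 8 arrays, IGKV12-98 on 6 and LOC636875 on 7, and in SPF WT mice H2-Q2 did so on 6 of 10 arrays. The loci LOC383308 and LOC675759 changed by -3.31 ± 0.80 and -2.57 ± 0.62, H2-Q2, an MHC class I gene, by -2.47 ± 0.72 and the glutathione transferase Gsta2 by -2.29 ± 0.34. Sdcbp2, a syntenin, the peroxisomal carrier Slc25a17 and Tomm22, of the mitochondrial import pore, changed by -2.28 ± 0.30, -2.22 ± 0.29 and -2.14 ± 0.59. For Tomm22 another probe, dim in all groups, gave 0.0064 ± 0.11. LOC383308 and Tomm22 were uneven in GF WT mice, with 5 and 4 of 8 arrays above every SPF WT array.

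Of 29 T cell genes, 14 were higher in SPF WT mice and none lower, and adjusted over the list alone 16 (median 0.49, adjusted p = 6.55e-12, and adjusted p = 0.0599 with an estimated correlation). Cd6 rose by 1.31 ± 0.27, Ccl5 by 1.19 ± 0.18 and Cd3e, a chain of the T cell receptor complex, by 1.01 ± 0.18. Some stromal genes rose as well: of 19 fibroblast and matrix genes 8 rose and none fell, and adjusted over the list alone 10 rose (median 0.27, adjusted p = 2.95e-07, and adjusted p = 0.0599 with an estimated correlation), and of 18 endothelial genes 3 rose and none fell, and adjusted over the list alone 5 rose and 1 fell (median 0.15, adjusted p = 0.000458, and adjusted p = 0.197 with an estimated correlation). Of 29 antimicrobial genes, 7 rose and none fell, and adjusted over the list alone 8 rose and 2 fell (median 0.23, adjusted p = 0.000458, and adjusted p = 0.369 with an estimated correlation), among them Nfkbiz, an NF-kappaB cofactor, at 0.74 ± 0.14. Of 28 xenobiotic genes, 10 fell and 1 rose, and adjusted over the list alone 11 fell and 1 rose (median -0.33, adjusted p = 2.91e-09, and adjusted p = 0.0599 with an estimated correlation). Gsta1, Gsta3 and the aldo-keto reductase Akr1c19 changed by -1.78 ± 0.27, -1.70 ± 0.20 and -1.62 ± 0.22, and Ahrr, a repressor of the aryl hydrocarbon receptor, rose by 0.50 ± 0.12. Of 21 myeloid and mast cell genes, 6 rose and none fell, and adjusted over the list alone 7 (median 0.24, adjusted p = 7.42e-05, and adjusted p = 0.254 with an estimated correlation). The mast cell genes Mcpt1, Fcer1a and Cpa3 rose by 1.49 ± 0.43, 1.27 ± 0.32 and 1.16 ± 0.33.

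Of 20 B and plasma cell genes, 5 rose and none fell in SPF WT mice, as adjusted over the list alone (adjusted p = 0.122). The list's median was -0.17, whereas its mean of 0.05 and camera's direction were upward. The genes that rose included the plasma cell genes Mzb1 at 1.72 ± 0.24, Tnfrsf17 at 1.33 ± 0.16 and Tnfrsf13b at 0.98 ± 0.25. GF WT animals 17.1 and 11.1 had B cell scores of 1.56 and 1.35, above a group median of -0.472. The simulation of this comparison recovered 55.2% of genes changed by 0.5, 92.5% of those changed by 1 and 100% of those changed by 2.

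In KO-labelled mice the SPF to GF difference was larger than in WT mice for the MHC class II and T cell lists. In that test the antimicrobial, type I interferon and B cell lists did not pass camera with an estimated correlation (adjusted p = 0.256, 0.256 and 0.448). The myeloid and mast cell list did not pass at the preset one either (adjusted p = 0.365). Saa1 was 31-fold higher in SPF than in GF KO-labelled mice, at 2418 ± 1916 (SD, n = 10) against 39.6 ± 23.1 (SD, n = 8), and was higher in all 10 SPF arrays than in any GF array. Cd6 rose by 3.55 ± 0.27 and the immunoglobulin segment IGHV1S28 by 4.43 ± 0.29. Of the clock genes 8 were lower and 2 higher, and of the adipose genes 5 were lower, with Dbp, a transcription factor driven by the clock, at -2.64 ± 0.59 and Cfd, the adipose protease adipsin, at -3.78 ± 1.31. Neither list passed camera with an estimated correlation (adjusted p = 0.257 and 0.336), and with the adipose score of each array as a covariate Cfd was at 0.015 ± 0.41. In all 3312 genes differed, 1529 higher and 1783 lower in SPF, and 405 at least 2-fold (283 higher, 122 lower). Between the WT and the KO-labelled comparison, which share no arrays, effects correlated across genes with Pearson's r = 0.607 and Spearman's rho = 0.408. In all 676 genes differed in both, 655 in the same direction (324 higher, 331 lower, against 60.0 and 64.8 for independent lists).

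The other highest genes of this comparison were again immunoglobulin segments or unnamed loci. Ighv1-84, IGHV1S30 and Igkv9-124 rose by 4.22 ± 0.39, 4.13 ± 0.34 and 3.62 ± 0.29, and LOC384415 and LOC100048770 by 3.98 ± 0.53 and 3.78 ± 0.29. Tomm22 and Slc25a17 changed by -2.82 ± 0.59 and -2.64 ± 0.29 in KO-labelled mice, where another probe of Tomm22 gave 0.11 ± 0.11. Cyp2e1, a cytochrome P450, Scd1, a desaturase, and Slc28a1 changed by -2.70 ± 0.65, -2.40 ± 0.65 and -2.43 ± 0.23. Cyp2e1 and Car3 passed detection on 1 of 10 SPF KO-labelled arrays and Cfd on 2, and Cd6, Car3 and Cfd on 5 of 8 GF KO-labelled arrays.

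Of the 31 MHC class II and interferon-gamma genes, 27 were higher in SPF KO-labelled mice and none lower, as adjusted over the list alone (median 1.77, adjusted p = 2.22e-33, and 0.00243 with an estimated correlation). H2-DMb1 rose by 3.14 ± 0.18, Igtp by 3.11 ± 0.39 and H2-DMb2 by 2.98 ± 0.20. Of 29 T cell genes, 21 rose and none fell, and adjusted over the list alone 23 (median 1.10, adjusted p = 1.17e-24, and 0.00175 with an estimated correlation), with Ccl5 at 2.72 ± 0.18 and Cd3e at 2.23 ± 0.18. Of 29 antimicrobial genes, 16 rose and 3 fell, and adjusted over the list alone 18 rose and 3 fell (median 0.62, adjusted p = 1.57e-10, and 0.0481 with an estimated correlation). Ubd rose by 3.41 ± 0.57 and Duoxa2 by 2.14 ± 0.34. Reg3a, the cornified-envelope protein Sprr2a1 and the decoy receptor Tnfrsf11b changed by -0.91 ± 0.12, -0.84 ± 0.17 and -0.37 ± 0.09. Of 29 cell cycle genes, 24 rose and none fell, and adjusted over the list alone 25 (median 0.49, adjusted p = 3.55e-19, and 0.0366 with an estimated correlation), with Plk1 at 0.91 ± 0.13, the kinase Aurka at 0.73 ± 0.09 and the mitotic activator Cdc20 at 0.70 ± 0.10. Of 20 B and plasma cell genes, 6 rose and none fell, as adjusted over the list alone (median 0.43, adjusted p = 6.44e-06, and adjusted p = 0.335 with an estimated correlation). Mzb1, Tnfrsf17 and Tnfrsf13b rose by 2.87 ± 0.24, 1.9 ± 0.16 and 1.79 ± 0.25. Single arrays stood apart in this list on both sides. SPF KO-labelled 114 had a score of 2.52 against a group median of 0.0635, and GF KO-labelled 11 one of 0.84 against -0.643.

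Of 15 clock genes, 8 were lower and 2 higher in SPF than in GF KO-labelled mice, as adjusted over the list alone (median -0.69, adjusted p = 0.01, and adjusted p = 0.257 with an estimated correlation). Arntl and Npas2, of the activating arm of the clock, rose by 1.36 ± 0.32 and 0.59 ± 0.19, and Tef and Ciart, of its output and repressing arms, changed by -1.75 ± 0.34 and -1.64 ± 0.39. Of 10 adipose genes, 5 fell and none rose, as adjusted over the list alone (median -0.87, adjusted p = 0.0037, and adjusted p = 0.336 with an estimated correlation). Car3, an abundant carbonic anhydrase of fat, and Adipoq, adiponectin, changed by -2.62 ± 0.87 and -2.27 ± 0.83. With the adipose score as a covariate the value of Adipoq became 0.19 ± 0.16, and with the clock score that of Ciart became 0.11 ± 0.18. The count of 3312 fell to 1597 with the clock score as a covariate. The simulation recovered 67.2% of genes changed by 0.5, 91.0% of those changed by 1 and 98.5% of those changed by 2.

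Sex was compared over all groups. X- and Y-linked genes followed the labels in all animals but 1. Xist, the RNA that coats the inactive X, was 17.8-fold higher in animals labelled female, a log2 difference of 4.15 ± 0.22, and the Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty differed by -3.90 ± 0.24, -2.23 ± 0.17, -1.70 ± 0.13 and -0.75 ± 0.08. The X-linked genes Kdm6a and Eif2s3x, which escape inactivation, were higher by 0.72 ± 0.07 and 0.52 ± 0.05, while Kdm5c and Ddx3x, at 0.05 ± 0.09 and 0.23 ± 0.10, did not pass. Of 9 measured sex-linked genes, 3 were higher in females, 4 lower and 2 not passed, and adjusted over the list alone 4 were higher and 4 lower. The list's median was 0.05, whereas its mean of -0.32 and camera's direction were downward (adjusted p = 0.232). SPF WT animal 122, labelled male, had a Xist intensity of 245.6 and 0 for Eif2s3y, and was kept as male in the values given here. Outside these genes, the mucosal pentraxin Mptx1 was higher in females by 0.95 ± 0.20, the neuropeptide Nmu by 0.62 ± 0.11, the matrix protein Mgp by 0.61 ± 0.12 and Slc40a1 by 0.61 ± 0.13. Another probe of Mptx1 gave -0.034 ± 0.09. Lower in females were Ada, adenosine deaminase, at -1.31 ± 0.27, the segment IGKV9-128 at -1.08 ± 0.26, the nucleoside transporter Slc28a2b at -1.05 ± 0.24, and Bambi-ps1 and 9130230L23Rik at -0.80 ± 0.17 and -0.69 ± 0.14.

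In all 79 genes differed between females and males, 40 higher and 39 lower in females, with animal 122 kept as labelled. With animal 122 entered as female, 103 genes were called, and 63 of these were among the 79. The count fell to 43 with the adipose score and to 39 with the interferon score of each array as a covariate. No gene had a genotype effect that differed between the sexes in limma's test, with 417 genes at an unadjusted p under 0.05. Of the lists, 2 passed camera at the preset correlation and 0 with an estimated one. The genotype effect was higher in females for type I interferon genes (median 0.59, camera adjusted p = 4.24e-10, and 0.956 with an estimated correlation). It was lower for antimicrobial genes (median -0.16, adjusted p = 0.0494, and 0.956). In GF WT mice the raised interferon scores were those of males 10.1, 11.1, 14.1 and 15.1 and female 17.1. The simulation of that test recovered 31.3% of differences of 0.5, 91.0% of differences of 1 and 98.5% of differences of 2.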

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

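The tests of the 3 patterns weighed here were chosen only after the result was seen, the lymphoid test replaced an earlier one, and the reading of the gene order test was changed after its value was known, while the splits of the arrays were planned. The limits written for counting values against the germ-free state alone were met in the clock and the Tomm22 test. In the clock test that reading was not applied, because most of the overlap came from WT mice.

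Ubd and Igtp were among the named genes whose genotype effect differed between SPF and GF mice by limma's test of the difference. Of 88 named genes examined, 45 differed, 25 with a higher and 20 with a lower effect in SPF. The 88 include genes named because this same test called them, so that share was partly fixed in advance. Over all tested genes, 581 of 15681 (3.71%) differed. The log2 differences (SPF effect minus GF effect) of the immune and interferon genes were 3.89 for Saa1, 3.70 for Ubd, 3.33 for Igtp, 2.74 for Irgm2, 2.62 for H2-Aa, 2.45 for Ifit2, 2.38 for Gm12250, 2.24 for Isg15, 2.24 for Cd6, 2.11 for H2-DMb2, 2.04 for H2-DMb1, 1.91 for Duoxa2, 1.86 for Psmb8, 1.53 for Ccl5, 1.38 for Nkg7, 1.15 for Lck and 0.85 for Il18. For Reg3a, Reg3b, Ifi202b and Defb37 they were -0.83, -1.25, -1.69 and -1.84. OTTMUSG00000016644 and 1810065E05Rik differed by 2.64 and 1.96. Of the transport and digestive genes, Slc2a2 differed by 2.10, Asah2 by 1.37, Mep1b by 0.29, Naaladl1 by -0.75, Slc26a6 by -0.78, Enpp7 by -1.05, Slc7a8 by -1.16 and Slc28a1 by -1.95. Plk1, Mcm5 and Birc5 differed by 0.68, 0.66 and 0.65. Fads2, Rbp2, Creb3l3, Slc25a48 and Cutal differed by -0.66, -0.70, -0.70, -0.72 and -1.01, and Cpne8, Asz1, Plscr4, Spsb4, Cyp2d40 and Cyp4f16 by -1.45, -1.56, -1.60, -1.60, -1.74 and -1.82. Saa1 and Slc25a48 were not above background on any GF WT array, so their differences depend on the offset added and are not exact. The same holds for 1810065E05Rik and Asz1, whose GF WT means lay under the detection threshold. The lists of MHC class II, T cell and cell cycle genes had median differences of 1.44, 0.78 and 0.44.

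Single arrays lay far from the rest of their group in 53 of 484 groups of values tested, 3 of 12 array measures, 7 of 68 list scores and 43 of 404 genes, where chance gives about 1 in 20 groups. Each value below is the gap from the extreme array to its nearest neighbour as a share of the group's range. SPF KO-labelled animal 114 had the lowest mean correlation with its group (0.756), the highest second principal component (0.536), the highest B cell (0.756) and T cell (0.608) scores and the lowest brush border (0.614), enteroendocrine (0.52) and ileal (0.568) scores. It was also highest for Lck (0.76), Mzb1 (0.503), Scd1 (0.57) and Tnfrsf13b (0.615) and lowest for Defb37 (0.501), Naaladl1 (0.468) and Slc7a9 (0.475). SPF KO-labelled animal 116 was highest for the adipose score (0.753) and for Adipoq (0.601), Car3 (0.938), Cfd (0.888) and Cyp2e1 (0.858).

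In the other SPF KO-labelled mice, animal 105 was highest for Fabp6 (0.639) and lowest for H2-Aa (0.608), and animal 130 lowest for Nkg7 (0.504). Animal 104 was highest for Ifi202b (0.525) and Lct (0.499) and lowest for Slc51b (0.623). In SPF WT mice, animal 117 had the lowest correlation with its group (0.5), was highest for Fads2 (0.488) and lowest for Suox (0.53). Animal 110 was lowest for Apoa4 (0.634), Cyp3a11 (0.534) and Slc51b (0.495), animal 122 highest for Amn (0.485), animal 106 highest for Defb37 (0.497) and animal 123 lowest for LOC636875 (0.658). In GF KO-labelled mice, animal 11 was highest for the B cell score (0.656) and Mzb1 (0.535), animal 14 lowest for Apoc2 (0.599), animal 16 highest for Cyp2b23 (0.741) and lowest for Gstm6 (0.54), and animal 10 highest for LOC384415 (0.53). Animal 15 was lowest for Dbp (0.698) and highest for Ifit2 (0.601) and Reg3b (0.72), animal 17 lowest for Ifi202b (0.591) and animal 12 lowest for Slc25a17 (0.596). In GF WT mice, animal 11.1 was highest for IGKV8-31 (0.531) and lowest for Slc1a1 (0.67), and animal 13.1 lowest for Slc25a17 (0.558). Animal 14.1 was highest for Slc51b (0.665) and lowest for Igkv7-33 (0.556), LOC675759 (0.676), Sdcbp2 (0.615) and Slc28a1 (0.683).

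The first pattern weighed was the lower level of type I interferon genes such as Isg15 in GF KO-labelled than in GF WT mice. Lymphoid tissue carried along is argued against as the whole cause, since without the arrays highest in B cell genes (7 KO-labelled and 6 WT left) the score still differed by -1.0 (two-sided exact permutation p = 0.00583). That p treats animals as independent, which they may not be. The scores themselves show it too: GF WT 10.1, 14.1 and 15.1 had interferon scores of 0.797, 1.74 and 1.12 with B cell scores of -0.442, -0.626 and -0.460, while 17.1 and 11.1 were raised in both. A few animals with a raised response may still account for it: the score differed in an exact permutation test (p = 0.000777), but neighbouring SPF animals were alike in it (autocorrelation 0.674, adjusted p = 0.00736 over 32 lists), so animals may not be independent. Loss of GATA4 acting in both microbial states cannot be told apart from no effect in SPF mice, where the difference was -0.017 (95% interval -0.687 to 0.654), an interval that just holds -0.633, which is 1/2 of the GF difference of -1.27.

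The second pattern was the difference of clock genes such as Dbp between SPF and GF KO-labelled mice. The germ-free state alone stays open: 7 of the 20 SPF arrays had a clock score inside the range of the GF arrays, but only 2 of these were KO-labelled, and ranges that overlap exclude nothing. A candidate explanation is the time of collection or another condition shared by animals with neighbouring numbers: their scores were alike (autocorrelation 0.584, one-sided permutation p = 0.00118, adjusted p = 0.0126 over 32 lists). Collection times are not given in the sources used here. For genotype and microbiota together, 1 of 15 clock genes had a lower genotype effect in SPF and 0 a higher one. The list did not pass (median -0.28, camera adjusted p = 0.102, and 0.448 with an estimated correlation). In SPF mice 5 clock genes were lower in KO-labelled mice (camera adjusted p = 0.00621, and 0.223 with an estimated correlation), and in GF mice 0 passed. In each pair of consecutive SPF numbers that held both genotypes, the KO-labelled animal had the lower clock score. The gaps ran from -0.599 against -0.494 (104 and 103) to -0.837 against -0.202 (114 and 113). A condition shared equally by neighbours would not give that gap, which concerns genotype within SPF and not the SPF to GF difference. A biological effect of both together stays open.

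The third pattern was a set of genes such as Tomm22 that were bright in some GF arrays and dim in SPF arrays. All 16 GF arrays share the germ-free state, yet 6 had a Tomm22 level inside the range of the SPF arrays. The GF medians were 385 in WT and 844 in KO-labelled mice, against a highest SPF level of 82.6. That state alone cannot give a split among GF arrays, so for this probe it is argued against as the whole cause. Tomm22 was picked because it shows the pattern, so for other genes the germ-free state alone stays open. A genetic difference between the colonies stays open too. It was tested on a wider set, 34 genes that differed at least 2-fold between SPF and GF in the same direction in both genotypes, most of them higher in SPF. Of these, 6 had another within 10 genes, against a mean of 1.67 in random sets (one-sided p = 0.0422), but so did 109 of 262 genes that differ between littermates, against 85.6 (p = 0.0094), and the test decides nothing about the pattern. The 6 were Cma2, Mcpt1, Sdcbp2, Srxn1, Gsta1 and Gsta2. Tomm22 and Slc25a17 both lie on chromosome 15, but neither had another gene of the set within 10 genes. The other probe of Tomm22 had group medians from 4.75 to 8.1 and a highest intensity of 17.4, so the difference rests on 1 probe.

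Whether a chance division of the arrays gives such counts was tested with 100 splits per count of genes, the real one included. As many genes as in the real split were called in 1 split for each of 6 comparisons, the real one. This is the lowest share that 100 splits can give, so a chance division is unlikely for those but not excluded. The splits also treat animals as independent, which neighbouring SPF animals may not be. They cannot address conditions shared by all animals of a colony. The real counts and the highest of the other splits were 3400 and 802 for genotype in SPF, 3091 and 1953 in GF, 581 and 9 for the difference between them, 1185 and 46 for SPF against GF in WT, 3312 and 707 in KO-labelled mice, and 79 and 2 for sex. For genotype by sex the real count was 0, which all 100 splits reach whatever the data (highest other 5), so this comparison says nothing about chance.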

How the results depend on the processing

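The tests with other offsets, without a floor, with changed or missing single arrays, without the 4 arrays highest in B cell genes, with paired consecutive numbers and with list scores as covariates were chosen only after the result was seen, and the others were planned.

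Fabp6, Lct and most other named genes kept their direction and their side of the threshold. Over 217 results for named genes, 3996 values under the alternatives did so, 136 kept the direction but lost the call, and 3 reversed. With 109 other probes of 77 genes, 84 values kept both, 19 lost the call, 1 gained it and 5 reversed. Of the values of the described lists, 92 kept both and 18 lost the call. The reversed values were 0.19 for Adipoq and 0.015 for Cfd in KO-labelled mice with the adipose score as a covariate, and 0.11 for Ciart with the clock score. In each case the gene belongs to the list whose score was removed. With other probes they were -0.015 for Nts in GF, 0.11 and 0.0064 for Tomm22 in KO-labelled and WT mice, -0.034 for Mptx1 between the sexes and 0.027 for Il18 in SPF mice, and the cause was not tested.

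The counts of genes ranged from 2838 to 3503 for genotype in SPF and from 2116 to 3409 in GF under the alternatives that moved them by less than 1.5 times. The corresponding ranges were 429 to 706 for the difference between them, 843 to 1326 for SPF against GF in WT, 2745 to 3489 in KO-labelled mice and 57 to 115 for sex. With the 23079 probes tested separately, 4648, 4110, 708, 1517, 4314 and 84 probes were called in these 6 comparisons. Fewer arrays gave fewer calls: 1169 genes in females and 2169 in males for genotype in SPF, and 1384 and 1628 in GF. For the difference between the genotype effects, 341 genes were called without the 4 arrays highest in B cell genes and 296 with the interferon score as a covariate. In KO-labelled mice 1597 genes were called with the clock score as a covariate, and between the sexes 43 with the adipose and 39 with the interferon score. Why these covariates lowered the counts was not tested. For genotype by sex, 1 gene was called with an offset of 50 and 1 without GF WT replicate 11.1, and 0 under the other alternatives.

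Without SPF WT 122, SPF KO-labelled 114, GF KO-labelled 11, GF WT 11.1 or GF WT 17.1, left out in turn, the counts ranged from 3199 to 3442 in SPF, 2796 to 3193 in GF, 447 to 575 for the difference, 1070 to 1277 in WT, 3001 to 3297 in KO-labelled mice, 53 to 92 for sex and 0 to 1 for genotype by sex. The correlation of genotype effects across genes ranged from 0.671 to 0.734, from 0.687 to 0.716 without single arrays, and was 0.559 with an offset of 1, where the cause was not tested. Of 68 list calls, 15 were made with an estimated correlation, and 72 without the filter and 67 without the sex term.

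Gata4 rose in SPF mice by 0.46 to 1.21 (adjusted p from 0.000568 to 0.0301), and by 0.77 to 0.79 without single arrays. In females alone the value was 0.61 ± 0.29 (adjusted p = 0.284), with fewer arrays. In GF mice it ranged from 0.27 to 0.75, and from 0.42 to 0.54 without single arrays. With the replicate block by number stem it was 0.48 (adjusted p = 0.0116, against 0.0116 to 0.679 over the alternatives), a call that the main design did not make. That block gave 3189 genes in GF and left the correlation at 0.697. By label, each GF KO-labelled animal shares its number stem and sex with a GF WT animal, but what the shared number means is not given. The deviations of animals with the same stem correlated between 0.0258 and 0.280, best with their own number in 5 of 8, a hint of pairing. Of the 8 correlations 2 lay under 0.1, so the numbers were not treated as pairs. Consecutive numbers taken as pairs gave 2838 genes in SPF.

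Not run were the alternatives without background correction, with median scaling and with the BeadChip as a block, and the main setting first planned, because the unnormalised columns match no label. Signal over background limits dim genes, for which the offset of 16 makes folds smaller.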

Other observations

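The tests of neighbouring animals and of the clock pair were chosen only after the result was seen, and the other values come from planned tests.

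Of 26 measured transcription factors of the gut, 8 rose and 5 fell in SPF KO-labelled mice (adjusted over the list alone 9 and 6, camera adjusted p = 0.422) and 9 rose and 5 fell in GF (adjusted over the list alone 11 and 5, adjusted p = 0.0713). Foxa1, a pioneer factor of endoderm, rose by 0.92 ± 0.07 and 1.03 ± 0.08, and Onecut2 by 0.80 ± 0.24 in SPF. Osr2 and Nr5a2 rose by 0.75 ± 0.07 and 0.72 ± 0.13 in GF. Hnf4g changed by -0.42 ± 0.12 and -0.58 ± 0.13, and Gata5 by -0.41 ± 0.13 and -0.44 ± 0.15.

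Of 17 genes of iron, calcium and metal absorption, 5 rose and 1 fell in SPF (camera adjusted p = 0.188) and 4 rose and 1 fell in GF (adjusted p = 0.0334, and adjusted p = 0.213 with an estimated correlation), as adjusted over the list alone in both. Slc40a1 rose by 2.77 ± 0.20 in GF mice, the zinc exporter Slc30a1 by 1.41 ± 0.12 in SPF and 1.31 ± 0.13 in GF, the metallothionein Mt1 by 1.26 ± 0.17 in SPF and the calcium pump Atp2b1 by 1.48 ± 0.12 in GF. The folate transporter Slc46a1 changed by -3.30 ± 0.22 and -1.90 ± 0.24. Of 23 genes of fatty acid oxidation, 8 fell and 1 rose in SPF, as adjusted over the list alone (camera adjusted p = 9.41e-05, and adjusted p = 0.179 with an estimated correlation), and 6 fell and 2 rose in GF, adjusted over the list alone 7 and 2 (adjusted p = 0.00631, and adjusted p = 0.38 with an estimated correlation). Acaa1b changed by -3.40 ± 0.23 and -1.95 ± 0.26, Acot12 (detected on 4 of 10 SPF KO-labelled arrays) by -2.92 ± 0.19 and -3.04 ± 0.21 and Pdk4 by -1.95 ± 0.27 and -1.98 ± 0.30, while Slc25a20 rose by 0.69 ± 0.13 and 0.73 ± 0.15 and Angptl4 by 1.79 ± 0.40 in GF. Of 21 goblet cell genes, 5 rose and 1 fell in SPF, as adjusted over the list alone (adjusted p = 0.0723), and 6 rose and none fell in GF, adjusted over the list alone 6 and 1 (adjusted p = 0.0461, and adjusted p = 0.489 with an estimated correlation). St6galnac1, Klk1 and Clca1 rose by 1.87 ± 0.19, 0.86 ± 0.12 and 0.35 ± 0.10 in SPF, Klk1 and Clca1 by 0.72 ± 0.13 and 0.65 ± 0.11 in GF, where St6galnac1, not above background on any GF WT array, was at least 1.64-fold higher, and Fcgbp changed by -0.44 ± 0.16 in SPF.

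Of 28 xenobiotic genes, 19 were lower in SPF than in GF KO-labelled mice and none higher (adjusted over the list alone 21 and 2, median -0.54, adjusted p = 3.7e-10, and 0.0366 with an estimated correlation). Gsta3, Gsta1 and the transporter Abcc2 changed by -1.99 ± 0.20, -1.81 ± 0.27 and -1.69 ± 0.22. Of 26 type I interferon genes, none passed between the sexes, and adjusted over the list alone 9 were lower in females (median -0.53, adjusted p = 1.06e-11, and adjusted p = 0.352 with an estimated correlation). This follows a few arrays: 8 of the 20 arrays labelled male and 1 of the 16 labelled female had an interferon score above 0, namely SPF animals 103 to 106 and GF WT 10.1, 11.1, 14.1, 15.1 and the female 17.1.

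Arntl, of the activating arm of the clock, and Dbp, which is driven by the clock, ran opposite within the SPF groups. In 10 SPF KO-labelled mice Pearson's r was -0.926 (permutation p = 0.00035), Spearman's rho -0.976 (permutation p = 1e-05, the smallest that 100000 resamples give) and r without the 2 farthest animals -0.882. In 10 SPF WT mice r was -0.966 (permutation p = 0.00013), rho -0.842 (permutation p = 0.00403) and r without the 2 farthest -0.965. These permutation p-values treat animals as independent, which neighbouring SPF animals may not be for clock genes, so they may be too small. Of the scores of 32 lists, 3 were alike in neighbouring SPF animals, those of interferon, immediate early (autocorrelation 0.579, adjusted p = 0.00992) and clock genes. Arrays 114 (SPF KO-labelled), 17.1 and 11.1 (GF WT) and 11 (GF KO-labelled) had the highest B cell scores, 2.52, 1.56, 1.35 and 0.84.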
